A study of Mus musculus with 4 samples.

How the data were processed

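RNA was measured by sequencing in 4 samples of mouse thymocytes at the DN3 stage, the CD4-negative, CD8-negative and CD25-positive stage at which T cell precursors rearrange their T cell receptor beta genes. Donor fetal liver cells, either wild type (WT) or carrying the Gata3(g/g) genotype that the labels call hypomorphic, had been transferred into irradiated recipients, and DN3 cells were sorted 16 weeks later. Each genotype had 2 samples, all labelled C57BL/6. Per the labels' protocols, RNA was purified on columns with DNase treatment and libraries were made with a NuGEN Encore Complete kit. Nothing in the labels says that the samples of a genotype came from separate animals, so the p-values concern the spread among these samples only. The tests estimate that spread in part from all tested genes together, not from each gene's own libraries alone. Xist and Y-linked transcripts differed between the 2 Gata3(g/g) samples, so these are not technical repeats of 1 sample. The 2 WT samples stood at 224 and 1.21 FPKM for Fos and at 0.663 and 237 FPKM for Hbb-b1, more than repeats of 1 RNA sample would differ.

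Per the submitters' processing notes, the authors used TopHat2 2.0.8b, Bowtie2 2.1.0 and Cuffdiff 2.1.1 with the mm10 mouse genome. The gene annotation, the read length and whether counting used the strand are not given in the sources used here. Values of overlapping genes, antisense genes, histone genes, globins and ribosomal protein genes with pseudogenes are therefore uncertain. Per the file headers, the authors deposited for each gene and library an estimated count of fragments before normalization between libraries and an FPKM value, a fragment count scaled by transcript length and by the mapped fragments of the library. The authors' deposited comparison table holds the mean FPKM of each genotype, a log2 fold change, a p-value and a q-value per gene. Gene positions are those of the authors' deposited table on mm10, written from 1. Gene symbols are those of the files.

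The per-library values covered 23285 genes. Of these, 3 genes whose locus Cuffdiff marked as too deep to estimate were left out, and 5 values marked as failed estimates were kept as deposited. In the comparison table, 84 entries join several gene symbols, and these were matched by their first symbol. Between 97.7% and 98.9% of the estimated counts in a library lay within 0.01 of a whole number, and all were rounded to whole numbers before testing. Rounded counts summed to 21159909 fragments in WT replicate 1, 14331705 in WT replicate 2, 26901913 in Gata3(g/g) replicate 1 and 18035342 in Gata3(g/g) replicate 2. With these totals, 3 fragments correspond to between 0.112 and 0.209 CPM, a floor that covers counting error only. The 10 most abundant genes took between 3.49% and 3.96% of each library.

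Before the data were examined, the samples, the 22 gene lists, the rule for named genes and most alternatives were fixed, and the planned main test was limma on log2(FPKM + 1). The deposited values turned out to include estimated counts, so the main test became edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the rounded counts, as that unit requires. This change was made before any test was run. Genes with a mean FPKM of at least 1 over the 4 libraries were tested (10224 genes), with trimmed mean of M values (TMM) scaling, factors from 0.983 to 1.02, a two-sided test and Benjamini-Hochberg adjustment at 0.05. The main model held the genotype alone and kept 2 residual degrees of freedom. The planned limma test (limma 3.58.1, pseudocount 1) is given beside it, as is DESeq2 1.42.0.

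The sequence identifiers in the labels place both replicates 1 in the same sequencing run, called run 1 here, and both replicates 2 in another, called run 2, so the replicate number marks a shared batch and pairs the samples. The pairing showed in the values: across the 10224 genes, the difference between the runs in WT and that in Gata3(g/g) had a Pearson correlation of 0.754 and a Spearman correlation of 0.758 (genes are not independent replicates). Whatever differed between the runs besides the sequencing itself is not given in the labels. Results of the model with the replicate block, which keeps 1 residual degree of freedom, are therefore printed beside the main ones. The block removes the run difference shared by the genotypes, and small p-values from that model lean on the spread pooled over genes. Fold changes, standard errors (SE) and adjusted p-values in the results are edgeR values with the block unless stated otherwise, list adjusted p-values, directions and medians are those without the block unless stated otherwise, and a positive log2 fold change means higher in Gata3(g/g). The SE is the absolute log2 fold change before edgeR shrinks it, divided by the square root of the F statistic. The printed log2 fold changes are the shrunken ones. Within-run differences are log2 CPM (counts scaled to library size) with a prior count of 2.

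Both models were tested on simulated data with 200 of the 10224 genes changed. The run differences were those averaged over the genotypes, hence the same in both, whereas in the data they correlated at 0.754. The simulated spread was that of the fit with the block, so the advantage of that model was built in. Its shares of recovered genes and false calls need not hold in the data. Without the block, none of the 100 genes changed 2-fold and none of the 100 changed 4-fold was recovered, and there were 0 calls. With the block, 88% of the genes changed 2-fold and 99% of those changed 4-fold were recovered, with 15 false calls among 202 (7.43%). A list shifted as a whole was called by the set test in both models, with 0 of the other lists called. Genes were drawn independently there, so false list calls from correlated genes were not tested. In the data, the estimated correlations within lists without the block ran from −0.315 (thymic stroma) to 0.988 (erythroid).

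Gene lists were tested with limma's camera, two-sided, with a preset correlation of 0.01 between genes and adjustment over the 22 lists, and again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. The lists were T-lineage transcription factors, pre-TCR and TCR signalling, V(D)J recombination, the Notch pathway, progenitor genes silenced at T commitment, DN2 to DN3 surface and cytokine receptors, Th2 and mature GATA3 targets, genes after beta selection, E and Id proteins, S phase, G2/M, p53 and apoptosis, interferon-stimulated genes, immediate-early stress genes, ribosomal proteins, histones, and markers of B-lineage, myeloid and dendritic, NK and innate lymphoid, gamma-delta T, erythroid and thymic stroma cells. Some lists share members, so their results are not separate signals. Of the measured members, 4 of 7 gamma-delta, 5 of 15 DN2 to DN3, 3 of 17 progenitor and 1 of 9 B-lineage genes are also in another list. List symbols absent from the files were looked up among the synonyms of the RefSeq GRCm38.p6 gene table. This lookup was added after values had been seen, and it matched 6 symbols, Spi1 (as Sfpi1) among them.

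Named genes followed a fixed rule: Gata3, then per direction the 10 largest changes past the limma threshold with the same sign in both runs, filled from genes past a q-value of 0.05 in the authors' deposited table whose libraries did not overlap between genotypes, then up to 4 members per list by size of change plus members past the threshold, to at most 8. Unnamed predicted genes were left out unless a list held them. The text prints part of the genes this rule names, picked after their values had been seen, and all of them enter the comparison of settings. For the lists, members past the threshold in the model with the block were counted as passing. Alternatives comprised other scalings, filters, pseudocounts and tests, the block, and leaving out each library in turn. Those combining the block with another choice, the list of structural ribosomal proteins and the symbols as first written were added after seeing the data.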

Results

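DN3 thymocytes derived from WT and from Gata3(g/g) fetal liver donors were compared by RNA sequencing, with 2 libraries of each genotype, the replicates 1 in sequencing run 1 and the replicates 2 in run 2. GATA3 is a zinc-finger transcription factor that T cell precursors need from their earliest stages, and Gata3(g/g) is labelled as a hypomorphic genotype. The comparison addresses the role of GATA factors at the DN3 stage. The libraries held between 14331705 and 26901913 fragments assigned to genes. Transcripts of the DN3 stage were abundant in all 4 libraries: Il2ra, which encodes CD25, stood at 277 and 261 FPKM in the WT libraries and 569 and 492 FPKM in the Gata3(g/g) libraries, and Dntt, the terminal transferase of T cell receptor rearrangement, at 789, 747, 1047 and 982 FPKM.

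Gata3 itself was higher, not lower, in the libraries labelled Gata3(g/g). It measured 62.4 and 58.5 FPKM in the WT libraries (60.5 ± 2.77, SD, n = 2) and 120 and 96.1 FPKM in the libraries labelled Gata3(g/g) (108 ± 16.8, SD, n = 2), from 4879 to 19243 fragments. The log2 fold change was 0.83 ± 0.146 (SE) by edgeR with the replicate block (adjusted p = 0.00166), and it was 0.96 in run 1 and 0.71 in run 2. Without the block the log2 fold change was 0.84 and did not pass (adjusted p = 0.965). In the authors' deposited table the Gata3 q-value was 0.00158. The gene lies on chromosome 2 from 9857078 to 9878600 in mm10, and a value per gene does not show which part of an altered allele was counted, and GATA3 protein was not measured. Directions given here for Gata3(g/g) rest on the labels.

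Genes that fell in the libraries labelled Gata3(g/g) included Cpa3, which encodes the mast cell protease carboxypeptidase A3, and Gzma, which encodes the cytotoxic granule protease granzyme A. Cpa3 fell from 43.5 and 50.0 FPKM in WT to 2.73 and 1.55 FPKM, a log2 fold change of −4.44 ± 0.212 (SE, adjusted p = 8.55e-10 by edgeR with the block). By limma with the block the Cpa3 adjusted p was 0.02265. Gzma fell from 485 and 463 FPKM to 98.3 and 96.1 FPKM, a log2 fold change of −2.28 ± 0.136 (SE). Fam163b (−3.12), Akr1c13 (−2.72), the growth-cone protein gene Basp1 (−2.69), the Rab GTPase gene Rab38 (−2.77), Spats2 (−2.65) and the imprinted noncoding RNA H19 (−2.01) fell as well, with standard errors of 0.149 to 0.319. Among increases, Ly86, which encodes the RP105-associated protein MD-1, rose from 0.879 and 1.24 FPKM to 9.02 and 16.9 FPKM, a log2 fold change of 3.56 ± 0.268 (SE, adjusted p = 2.57e-07 by edgeR with the block). The cytochrome oxidase subunit gene Cox6a2 (3.23), the interferon-induced membrane protein gene Ifitm1 (3.22), B4galnt2 (3.16), the actin-severing scinderin gene Scin (2.12) and the myoferlin gene Myof (1.92) rose. Slc15a2, a peptide transporter gene, rose by 1.74 ± 0.420 (SE), but its difference was 3.23 in run 2 and 0.31 in run 1, so that Gata3(g/g) replicate 2 decided its size. The noncoding transcript I730028E13Rik, singled out after its values were seen, rose from 1.46 and 1.22 FPKM to 33.2 and 45.0 FPKM.

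**Figure D1:**
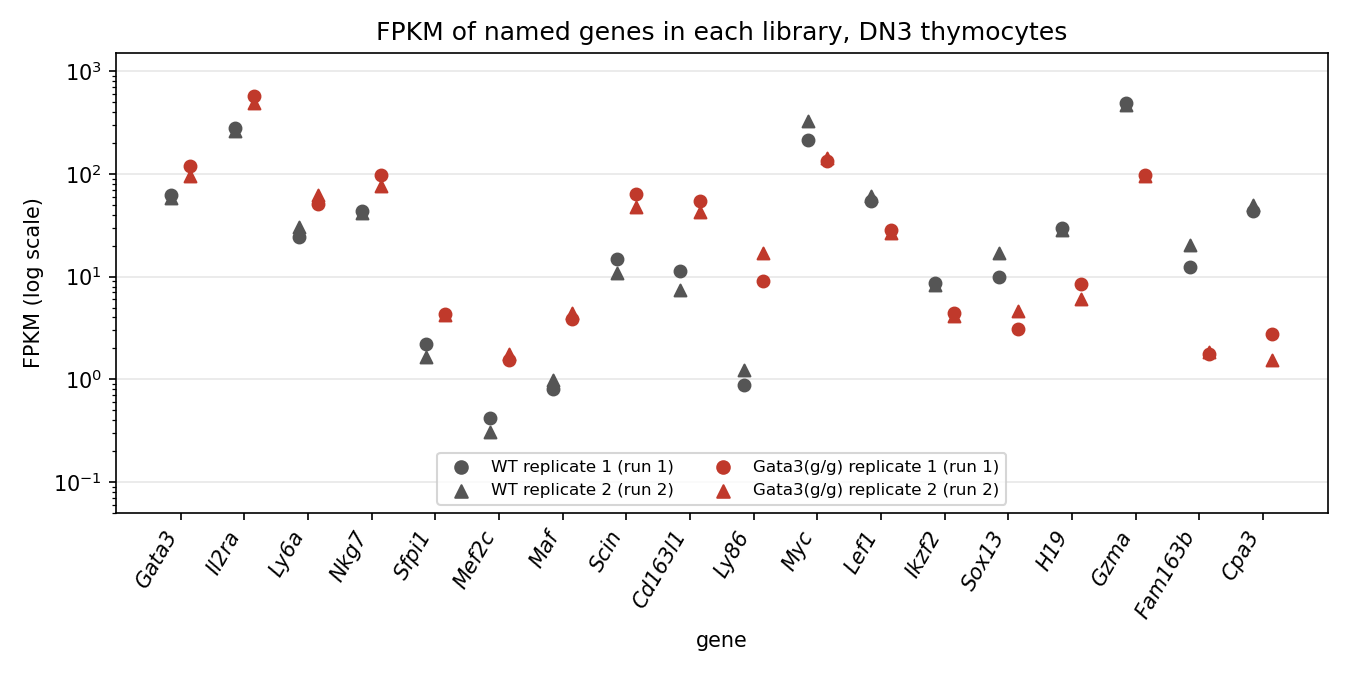
FPKM on a log axis for 18 named genes in each of the 4 libraries, grey for WT, red for Gata3(g/g), circles for run 1 and triangles for run 2, 1 point per library. Gata3 sits at 62.4 and 58.5 FPKM in WT and at 120 and 96.1 FPKM in Gata3(g/g), while Cpa3 goes from 43.5 and 50.0 FPKM to 2.73 and 1.55 FPKM.

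Across all 10224 genes, the model with the block called 705 genes, of which 399 were higher and 306 lower in Gata3(g/g). More than 2-fold changes numbered 122 higher and 81 lower, and 699 of the 705 had the same sign in both runs. That share follows largely from the selection, since the model with the block favours genes whose 2 within-run differences agree. The main edgeR model, without the block, called 0 genes at an adjusted p under 0.05, the smallest being 0.0995 (I730028E13Rik). It gave 393 genes with an unadjusted p under 0.05 against 511.2 by chance, in a model that ignores the pairing by run, and the model with the block gave 2140. Without the block, DESeq2 called 88 genes and limma 5, and with it DESeq2 called 417 and limma 18. The 5 limma calls were I730028E13Rik and the small RNA genes Snord82, Mir5133, Mir1949 and Snord12, which had at most 3 fragments in any library and of which none passed edgeR with or without the block. With the block but no scaling beyond total fragments, 464 of 674 calls were higher, 68.8% against 56.6%, and the median of all genes lay at 0.06 in place of 0.01 on the log2 scale.

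The authors' deposited table called 456 genes at a q-value under 0.05, 255 higher and 201 lower in Gata3(g/g). Of the 428 that were also tested here, 410 (95.8%) passed edgeR with the block, all 410 in the same direction, and 15 passed limma with the block. Both tests used the same 4 libraries, so the shared direction was largely given and the overlap is no independent support. Libraries of the 2 genotypes did not overlap for 3004 genes (29.4%), where chance gives 33.3% for exchangeable libraries, a figure that ignores the pairing by run. Libraries of the same run but different genotype were closer to each other, with Pearson correlations of log2(FPKM + 1) across genes of 0.953 in run 1 and 0.939 in run 2, than libraries of the same genotype, 0.888 for WT and 0.924 for Gata3(g/g). Between the runs, the genotype differences correlated across genes at 0.216 (Pearson) and 0.430 (Spearman), and 64.1% of genes had the same sign. This correlation was taken over genes, which are not independent replicates, as a description.

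**Figure D2:**
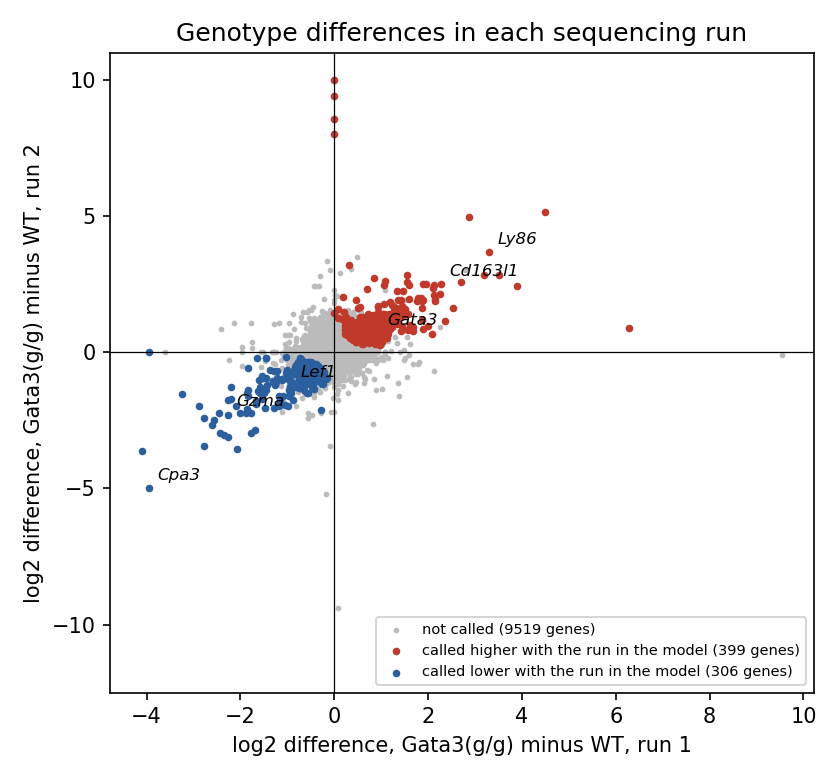
Log2 difference between the Gata3(g/g) and the WT library in run 1 (x axis) and in run 2 (y axis) for each of the 10224 genes, with calls of edgeR with the block in red (399 higher) and blue (306 lower). Of the 705 called genes, 699 have the same sign in both runs, which the selection by that model favours. On the y axis, 4 Y-linked genes sit from 8.02 (Uty) to 10.01 (Eif2s3y), at 0 on the x axis.

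Of 17 measured progenitor genes that are normally silenced as T cells commit, 7 rose in Gata3(g/g), 1 fell and 9 did not pass. Mef2c, a transcription factor gene of lymphoid and myeloid progenitors, rose from 0.420 and 0.304 FPKM to 1.56 and 1.76 FPKM (log2 fold change 2.19 ± 0.242, SE). Sfpi1, the older symbol of the gene for the myeloid and B cell factor PU.1, rose from 2.20 and 1.63 FPKM to 4.34 and 4.25 FPKM (1.17 ± 0.276, SE, adjusted p = 0.0159 by edgeR with the block). The homeobox gene Hoxa7 (1.29), the adhesion receptor gene Cd44 (1.23), Ly6a, which encodes the stem cell antigen Sca-1 (1.05), Nfe2 (0.87) and Mycn (0.65) rose too, whereas Zfpm1, which encodes the GATA cofactor FOG-1, fell by 0.75 on the log2 scale. The list passed camera in the upward direction without the block (adjusted p = 1.54e-08) and with it (adjusted p = 4.06e-06), but not with an estimated correlation (adjusted p = 0.402). Sfpi1 entered the list through the symbol lookup made after values had been seen, and with the symbols as first written the list adjusted p was 2.54e-07. Adjusted over the list alone, 3 members passed without the block and 9 with it.

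Genes of gamma-delta T cells moved in both directions. The scavenger receptor genes Cd163l1 (2.39 ± 0.131, SE) and 5830411N06Rik (2.29 ± 0.136, SE), the transcription factor gene Maf (2.22 ± 0.198, SE) and the kinase gene Blk (1.82 ± 0.184, SE) rose. Sox13, a transcription factor gene of early gamma-delta cells, fell by 1.79 ± 0.143 (SE), from 13.5 ± 5.14 to 3.83 ± 1.09 FPKM (SD, n = 2). The other 2 of the 7 measured members did not pass. The list passed camera upward without the block (adjusted p = 8.95e-07) and with it (adjusted p = 8.19e-12), but not with an estimated correlation (adjusted p = 0.402), and 4 members without the block and 5 with it passed adjusted over the list alone. Cd163l1 and 5830411N06Rik are related neighbours on chromosome 7, and fragments may have been shared between them.

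Of 15 measured receptors of the DN2 and DN3 stages, 5 rose and 0 fell. Those that rose were Il2ra (0.98 ± 0.181, SE), Cd44 (1.23), the interleukin 7 receptor gene Il7r (0.70), the chemokine receptor gene Cxcr4 (0.56) and the cytokine receptor subunit gene Il6st (0.46). The list passed camera without the block (adjusted p = 0.00999) and with it (adjusted p = 0.0106), but not with an estimated correlation (adjusted p = 0.848). Its call was also lost without WT replicate 1 (adjusted p = 0.379) and without Gata3(g/g) replicate 2 (adjusted p = 0.116), and with no filter (adjusted p = 0.411, and 0.102 with the block). Adjusted over the list alone, 0 members passed without the block and 5 with it.

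Among 23 measured T-lineage transcription factors, Gata3 rose, 3 fell and 19 did not pass. Lef1, which encodes a partner of TCF-1, fell from 53.8 and 61.4 FPKM to 28.4 and 26.7 FPKM (log2 fold change −1.06 ± 0.127, SE, adjusted p = 4.76e-05 by edgeR with the block). Ikzf2, which encodes the Ikaros family member Helios, fell (−0.98), as did the chromatin organizer gene Satb1 (−0.57, with −0.77 in run 1 and −0.37 in run 2). The list as a whole did not pass camera (adjusted p = 0.633), and its median of 0.09 and its mean of −0.02, both without the block, had opposite signs. Adjusted over the list alone, 2 members passed without the block and 5 with it.

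Of 15 measured genes of the Notch pathway, which directs T cell commitment, 2 rose and 2 fell. Dtx1, a Notch target, rose from 19.3 and 18.6 FPKM to 41.7 and 33.0 FPKM (0.98 ± 0.128, SE), and Il2ra rose, while Trib2 (−1.72) and Myc (−0.93 ± 0.175, SE), the growth regulator, fell. The other 11 did not pass and neither did the list (adjusted p = 0.67). Of 27 measured genes of pre-TCR and TCR signalling, Themis (0.80), the phosphatase gene Ptpn22 (0.61) and Cd6 (0.52) rose and 24 did not pass (list adjusted p = 0.343). Of 14 measured V(D)J recombination genes, 1 passed, the ligase gene Lig4, which fell (−0.59). Dntt had a log2 fold change of 0.41 (adjusted p = 0.202) and Rag1 of −0.40 (adjusted p = 0.262), with −0.78 in run 1 and −0.00756 in run 2 and a direction that turned on leaving out 1 library, and the list adjusted p was 0.565. With the block and adjusted over the list alone, 6 Notch, 3 TCR and 2 V(D)J members passed, against 0 in each list without the block.

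Genes that change after beta selection, the checkpoint that follows DN3, moved both ways. Of 18 measured members, the coreceptor genes Cd8b1 (1.77 ± 0.302, SE, with 1.08 in run 1 and 2.64 in run 2) and Cd8a (1.28 ± 0.286, SE) rose, from levels of at most 3.63 FPKM in WT. Aqp11 (−0.91), the amino acid transporter genes Slc7a5 (−0.68) and Slc3a2 (−0.45) and the immediate-early gene Egr1 (−0.73) fell. Egr1 was −0.74 in run 1 and −0.72 in run 2. Leaving out 1 library, which leaves the runs unequally shared between the genotypes, turned the direction of Egr1. The list did not pass (adjusted p = 0.979), except downward with the block at a mean FPKM of at least 5 (adjusted p = 0.0342), while adjusted over the list alone 0 members passed without the block and 8 with it. None of the 30 measured S-phase genes or the 30 measured G2/M genes passed by edgeR with the block, alone or adjusted over the list alone (list adjusted p = 0.147 and 0.885), the largest differences being −0.39 for Chaf1b and −0.38 for Plk1. The S-phase list passed downward without WT replicate 2 (adjusted p = 0.00373) and without Gata3(g/g) replicate 1 (adjusted p = 0.0427), and with the block under no filter (adjusted p = 0.021) or limma (adjusted p = 0.0492). Of 19 p53 and apoptosis genes, Pmaip1 (1.32, with 0.69 in run 1 and 2.33 in run 2) and Trp53inp1 (0.73) rose and Bbc3, which encodes the proapoptotic protein PUMA, fell (−1.26), with a list adjusted p of 0.565. Of 7 measured E and Id protein genes, Id2 rose by 0.77 ± 0.224 (SE, adjusted p = 0.0487, list adjusted p = 0.343), mostly in run 2 (1.48, against 0.20 in run 1), and leaving out 1 library turned its direction. With the block, adjusted over the list alone, 3 of the p53 and 1 of the E and Id genes passed, against 0 without it.

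Of 93 measured genes whose symbols start as ribosomal protein genes do, 13 fell and 1 rose. Rps19 (−0.73 ± 0.140, SE, with −0.48 in run 1 and −0.98 in run 2), Rpl11 (−0.67), Rpl22 (−0.63) and Rps21 (−0.61) fell, as did the kinase-like gene Rps6kl1 (−1.33), which is not a ribosomal protein gene. The structural ribosomal proteins alone passed camera downward without the block (adjusted p = 1.68e-07). Their median log2 fold change was −0.31 by limma and −0.11 by limma after quantile normalization, so its size depended on the scaling. The full list passed camera downward without the block (adjusted p = 8.15e-10), with it (adjusted p = 5.55e-09) and after quantile normalization (adjusted p = 0.0025). It did not pass with an estimated correlation (adjusted p = 0.812). The median of the full list was −0.44 in run 1 and −0.20 in run 2. Adjusted over the list alone, 0 members passed without the block and 33 with it. Of 63 measured histone genes, 11 fell and 2 rose. Hist1h3f (−2.33), Hist1h4d (−1.56) and Hist1h3e (−1.23, with −0.28 in run 1 and −2.12 in run 2) were among those that fell. Hist2h4 (0.69, with 0.68 in run 1 and 0.70 in run 2) was among those that rose. The direction of Hist2h4 turned on leaving out 1 library, which leaves the runs unequally shared between the genotypes. Adjusted over the list alone, 18 passed with the block and 0 without. The histone list passed with the block (adjusted p = 0.00277) but not without it (adjusted p = 0.0734) nor with the block and an estimated correlation (adjusted p = 0.754), it passed without the block under no filter (adjusted p = 0.0169), and it passed in the opposite direction without WT replicate 2 (adjusted p = 0.00216) and without Gata3(g/g) replicate 1 (adjusted p = 8.75e-05).

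The 23 measured interferon-stimulated genes were higher as a list by camera (adjusted p = 0.028 without the block and 0.0241 with it), but not with an estimated correlation (adjusted p = 0.812). None passed alone, whether adjusted over all genes or over the list alone. The antiviral gene Mx1 had a log2 fold change of 0.99 (adjusted p = 0.0687 by edgeR with the block) and Isg15 of 0.57 (adjusted p = 0.122, with 0.27 in run 1 and 0.91 in run 2). The list adjusted p was 0.244 without WT replicate 2 and 0.369 without Gata3(g/g) replicate 1, 0.089 with no filter and 0.116 at a mean FPKM of at least 5 (0.119 with the block). Of the 4 measured Th2 and mature GATA3 targets, Maf rose and Il17rb, a cytokine receptor gene, fell from 47.2 and 43.7 FPKM to 27.9 and 21.7 FPKM (−0.88 ± 0.129, SE). That list did not pass (adjusted p = 0.649), its median of −0.23 without the block and its upward test differed in sign, and 2 members passed adjusted over the list alone with and without the block.

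**Figure D3:**
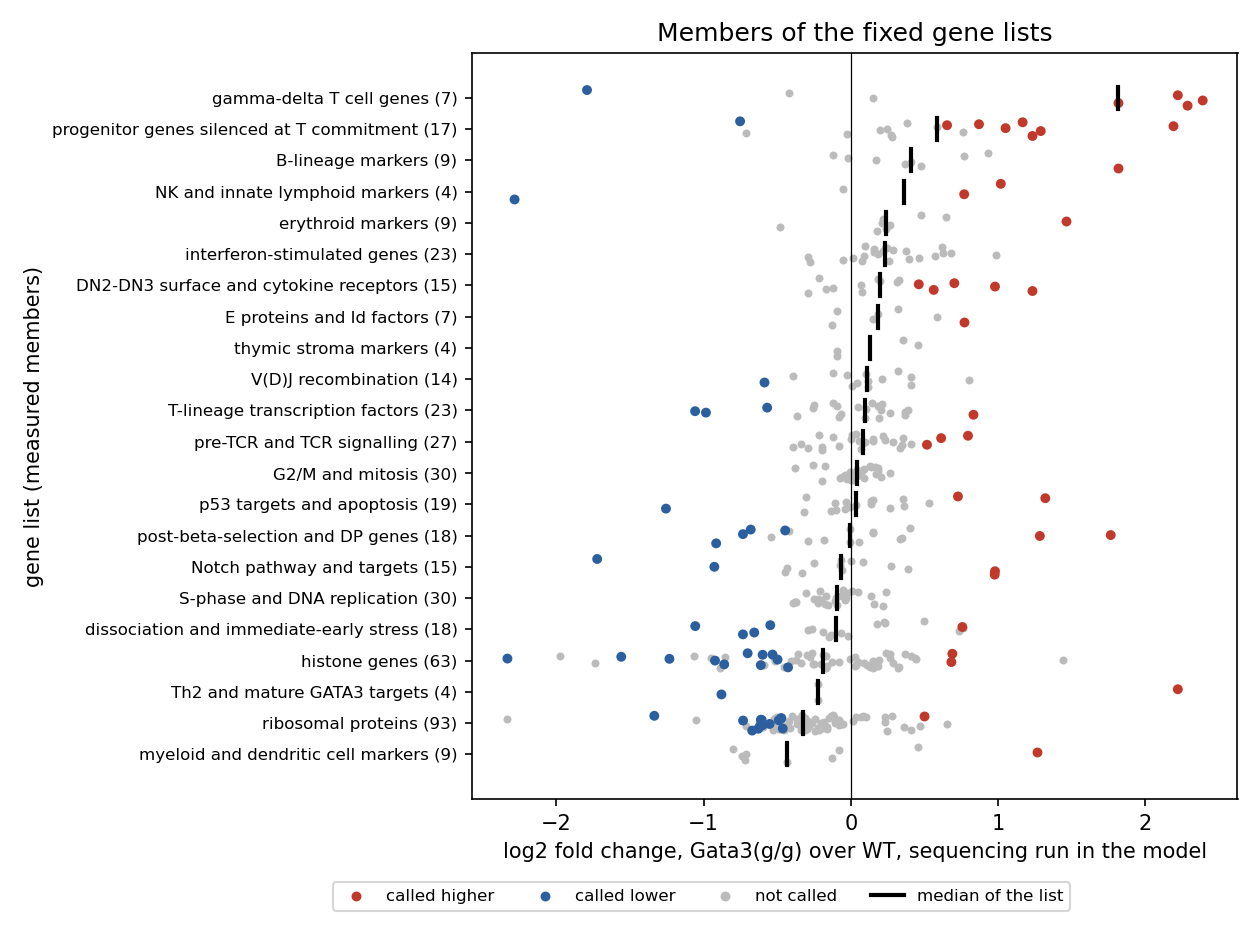
Log2 fold changes with the block (x axis) of the measured members of the 22 fixed gene lists (y axis, number measured in brackets), coloured where called, with a black bar at the median of each list. The gamma-delta list has the highest median (1.82) and the myeloid and dendritic list the lowest (−0.43).

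Of 9 measured B-lineage markers, only Blk passed, which is also on the gamma-delta list. The B-lineage list passed camera upward without the block (adjusted p = 0.00999) and with it (adjusted p = 0.00657). With an estimated correlation its adjusted p was 0.848, without WT replicate 2 it was 0.278 and without Gata3(g/g) replicate 1 it was 0.233, with no filter it was 0.356 (0.109 with the block), and at a mean FPKM of at least 5 it was 0.102. Of 9 myeloid and dendritic markers, the lysozyme gene Lyz2 rose by 1.27 ± 0.198 (SE) and 8 did not pass, the list median being −0.52 without the block (list adjusted p = 0.562) and −0.43 with it (adjusted p = 0.382). Of 4 NK and innate lymphoid markers, Nkg7, which encodes a cytotoxic granule protein, rose (1.02 ± 0.140, SE), Id2 rose and Gzma fell. The NK list did not pass (adjusted p = 0.562), and its median of 0.13 without the block (0.36 with it) and its downward test differed in sign, while without WT replicate 2 it passed downward (adjusted p = 0.0132). None of the 4 thymic stroma markers passed (list adjusted p = 0.565). Adjusted over the list alone with the block, 1 B-lineage, 2 myeloid, 3 NK and 2 stroma markers passed, and without it 2 NK markers did.

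Haemoglobin transcripts differed far more between the runs than between the genotypes. Hbb-b1 measured 0.663 FPKM in WT and 2.15 FPKM in Gata3(g/g) in run 1, against 237 and 224 FPKM in run 2. Among 9 measured erythroid markers, Hba-a2 passed (1.46 ± 0.376, SE), with fragments in run 2 libraries alone and a direction that turned on leaving out 1 library, and the list did not (adjusted p = 0.418 with the block, upward with a median of 0.24, and 0.979 without it, downward with a median of 0.22). Immediate-early genes went the other way: Fos measured 224 and 152 FPKM in run 1 and 1.21 and 2.22 FPKM in run 2. Within runs, Junb (−1.06, with −1.37 in run 1 and −0.64 in run 2), Egr1, Fosb (−0.66) and Jund (−0.55) fell in Gata3(g/g) and Jun rose (0.76, with 0.26 in run 1 and 1.29 in run 2), out of 18 measured (list adjusted p = 0.71), and each of these 5 genes turned direction on leaving out 1 library. Leaving out any 1 library, which leaves the runs unequally shared between the genotypes, made both lists pass, with adjusted p-values of at most 0.00165 for the erythroid and 1.44e-05 for the immediate-early list, in directions that changed with the library. With the block, 6 of the immediate-early genes and 1 of the erythroid genes passed adjusted over the list alone, and without it 0 did. Y-linked transcripts were present in Gata3(g/g) replicate 2 alone, with Eif2s3y at 56.9 FPKM there and at most 0.0228 FPKM elsewhere, and 4 of the 705 called genes lay on the Y and 17 on the X chromosome. Xist, the X-inactivation transcript, measured 30.2, 90.9 and 31.9 FPKM in WT replicates 1 and 2 and Gata3(g/g) replicate 1 and 0.145 FPKM in Gata3(g/g) replicate 2, so the genotypes differed in sex in run 2.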

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

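Settings that join the block with another choice, the structural ribosomal list and the list symbols as first written were chosen after seeing the data. The count of changed genes, 0 in the main model, was 705 with the replicate block. Without the block it was 0 at a mean FPKM of at least 5 and with median of ratios scaling, 58 with no filter, 88 with DESeq2, 5 with limma, with limma at pseudocount 0.1 and with limma without a variance trend, 3 with limma after quantile normalization, and 428 by the authors' Cuffdiff q-values. With the block it was 18 with limma, 417 with DESeq2, 988 with no filter, 348 at a mean FPKM of at least 5, 725 with median of ratios scaling and 674 with total fragments only. Leaving out each library in turn gave 1 to 11 genes. There a lone library is assumed to vary like the pair of the other genotype. The block would leave no residual degrees of freedom, so it was left out and the runs were unequally shared between the genotypes. Part of the difference between settings follows from the number of genes tested, and otherwise the cause was not tested except for the block.

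Gata3 stayed higher under every setting run. Its log2 fold change passed with the replicate block at 0.83, also with DESeq2, no filter (0.83 each) and median of ratios scaling (0.83), at 0.85 with a mean FPKM of at least 5, at 0.88 with total fragments only, and at 0.84 by Cuffdiff. It did not pass in the other settings, limma with the block among them (adjusted p = 0.126). Leaving out each library gave 0.68 to 0.99.

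The 6 lists passing camera became 7 with the block and 0 with an estimated correlation or fry's one-way test, each with and without the block. Leaving out a library gave 8 to 9. By camera with an estimated correlation, the smallest adjusted p of any list was 0.402 without the block and 0.754 with it. That test rests on 2 residual degrees of freedom, or 1 with the block, so a list failing it is not thereby shown to be unchanged. Fry's mixed test, for change in either direction within a list, passed some lists without the block. Its adjusted p was 0.0148 for the T-lineage, Notch, progenitor and NK lists. It was 0.0247 for the Th2, 0.0467 for the DN2 to DN3 receptor and 0.0472 for the gamma-delta and post-beta-selection lists. With the block no list passed the mixed test, the smallest adjusted p being 0.0792. By camera, the Th2 list passed downward at a mean FPKM of at least 5 without (adjusted p = 0.0191) and with the block (0.019). Adjusted p-values over the left-out libraries, in changing directions, ran from 1.06e-11 to 0.00165 for the erythroid, 6.42e-09 to 1.44e-05 for the immediate-early and 2.3e-19 to 0.00216 for the histone list. The Pearson correlation of the log2 FPKM genotype differences between the runs was 0.197 at pseudocount 0.1 and 0.173 at a mean FPKM of at least 5. The authors' table held 215 genes at q under 0.01.

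Besides Gata3, 117 genes were compared: all that the fixed rule names, printed elsewhere in the text or not, and 1 more. Of 1808 values under other settings, 554 newly passed, mostly with the block, and 14 changed direction, all in Ifng and Hbb-b1. The log2 fold change of Ifng turned to 0.66 with limma at pseudocount 0.1, 0.0155 with quantile normalization and 1.95 with DESeq2 and the block. That of Hbb-b1 turned to 0.42 with limma, with or without the variance trend or the block, 0.74 at pseudocount 0.1 and 0.47 with quantile normalization. With the block it was 0.22, also at a mean FPKM of at least 5, 0.21 with median of ratios scaling, 0.26 with no filter and with total fragments only, and 0.75 with DESeq2. Fits without 1 library held no block, so run differences enter their values. Of 468 such values, 36 changed direction, in 24 genes. Their log2 fold changes ran from −1.01 to 0.24 for Rag1, −0.0894 to 0.77 for Cd72, −1.83 to 0.58 for Cebpb, −9.31 to 3.13 for S100a9, −0.13 to 1.90 for Id2, −4.27 to 10.13 for Ifng, −1.92 to 0.45 for Egr1, −0.47 to 0.0292 for Rad50. Others ran from −0.0611 to 0.57 for Cenpf, −0.34 to 0.80 for Cdc20, −9.39 to 10.96 for Hba-a2, −5.76 to 7.39 for Hbb-b1, −9.79 to 10.87 for Beta-s, −7.77 to 8.80 for Slc4a1, −0.0485 to 0.99 for Ly75, −0.47 to 0.32 for Epcam. The rest ran from −0.64 to 0.53 for Ccl25, −3.16 to 1.21 for Junb, −1.01 to 2.69 for Jun, −2.07 to 0.94 for Jund, −6.52 to 5.29 for Fosb, −3.40 to 1.37 for Hist1h2bl, −1.74 to 0.0726 for Hist1h2ag, −2.04 to 3.42 for Hist2h4. With 2 libraries per genotype and 14331705 to 26901913 fragments, depth limits genes of a few fragments, such as Snord82.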

Other observations

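The tests of run difference, sex, scaling, exchanged labels and myeloid cells were chosen after the result was seen, as were the genes named in this part. Beyond the fixed lists, single genes were picked by their values and not tested as a group, and the following were higher in the libraries labelled Gata3(g/g), by edgeR with the replicate block. Ly6d, a marker of lymphoid progenitors with B cell potential, rose from 290 and 251 FPKM to 608 and 649 FPKM (log2 fold change 1.22, adjusted p = 3.5e-05). The lysosomal protease gene Ctss rose from 1.78 and 0.956 FPKM to 6.14 and 4.03 FPKM, the lectin receptor gene Clec12a from 9.20 and 6.60 FPKM to 20.7 and 24.0 FPKM, and Slamf6 from 17.9 and 10.6 FPKM to 33.7 and 29.7 FPKM. The homeobox gene Hoxa5, a neighbour of Hoxa7, rose from 2.18 and 1.69 FPKM to 5.85 and 6.51 FPKM. Bst1 and the neuropilin gene Nrp1 also rose, by 0.91 and 0.94 on the log2 scale.

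The nuclear receptor genes Nr4a1, Nr4a2 and Nr4a3, which antigen receptor signals induce, fell, with log2 fold changes of −1.21, −1.57 and −1.53, and the levels of all 3 were higher in run 1 than in run 2 within each genotype. The kinase gene Camk4 (−1.09), the histone deacetylase gene Hdac7 (−0.74), the growth factor receptor gene Igf1r (−1.73) and the Hedgehog transducer gene Smo (−1.36) fell, Igf1r from 4.52 and 7.87 FPKM to 1.42 and 2.27 FPKM. Srm, the spermidine synthase gene, fell from 152 and 146 FPKM to 104 and 76.6 FPKM.

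By edgeR at the main filter, no gene passed without the sequencing run in the model and 705 did with it. The counts without and with the run were 88 and 417 by DESeq2, 5 and 18 by limma, and 58 and 988 by edgeR with no filter. With every library thinned to the total of the smallest, 0 genes passed edgeR without the run and 427 with it, all 427 among the 705. A gap thus remained at equal depth. The fit without the run passed 0 genes at full depth too, and thinning only removes fragments. Its 0 could therefore hardly have changed, and unequal depth as a cause of that 0 stays undecided. A difference between runs shared by both genotypes may widen the spread, since the run differences of WT and Gata3(g/g) correlated at 0.754. The sex of Gata3(g/g) replicate 2 as a part of the run 2 difference cannot be told apart from the genotype. The 200 genes with the largest log2 CPM difference in run 2 were taken, off the sex chromosomes and at a mean FPKM of at least 5. Their median was 1.21 in run 2 and 0.46 in run 1 signed by run 2, a share of 38.0%. The sign was the same in 147 of them (73.5%), and picking genes by run 2 inflates the run 2 value. The 64.1% of all genes is an unlike share, as it was taken on log2(FPKM + 1) without these filters. What made the runs differ stays open, and the genotype as the source of the 705 genes was tested in 1 library pair per run only.

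Gata3 RNA was higher in both libraries labelled Gata3(g/g). Scaling is argued against by the smallest log2 fold change over 4 scalings, 0.83. A regional change cannot be told apart from none: genes within 10 Mb of Gata3 were called 1.21 times as often as others (4 of 48, Fisher's exact p = 0.571, odds ratio interval 0.32 to 3.39). The bound set beforehand against it, a ratio under 1.5 without a passing p-value, was met, but the interval includes 2-fold, a condition added after the value was seen. The 48 genes had a median log2 fold change of 0.03 with the block, against 0.83 for Gata3. The 4 called ones moved both ways: 9230102O04Rik (4.17), Il2ra (0.98) and Otud1 (0.92) rose and Nebl fell (−1.07). Among these 4 called genes, 9230102O04Rik, on chromosome 2 from 9881246 to 9889540 and inside the longer Gata3 gene of GENCODE M21 (to 9890034, same strand), had 5 and 0 fragments in WT and 65 and 55 in Gata3(g/g), so transcription from upstream in the altered locus is a candidate source, untested here. Labels exchanged in both runs could give the same values, since Gata3 was higher in the Gata3(g/g) library in 2 of 2 runs, and stay open, as does a response of the locus to less GATA3 protein.

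Mef2c, Sfpi1, Ly86 and Lyz2, which are known from progenitors or myeloid cells, rose, while Tyrobp did not pass (0.46, adjusted p = 0.451). More myeloid cells in the sorted samples would raise the markers that those cells carry, which need not be the whole list. The 9 measured ones had a median log2 fold change of −0.43 with the run in the model (standard error of the mean 0.231), and 7 of the 9 were below 0. For the 4 with a mean FPKM of at least 5 the median was 0.19 (standard error 0.436), so that with 4 markers at that level more myeloid cells cannot be told apart from none. A shift in the stages that passed the sort was not tested.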
